A study of Mus musculus with 7 samples.

How the data were processed

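Uteri of 7 mice on day 5 of pregnancy were profiled by droplet single-cell RNA sequencing (10x Genomics). The 4 knockout mice carried floxed Lcn2 and a Cre allele, which the labels describe as deleting Lcn2 in epithelial and stromal cells of the endometrium, and the 3 control mice carried floxed Lcn2 alone. Each library came from 1 mouse, so the mouse was the replicate throughout. Per the labels' protocols, a blue dye was injected into the circulation to mark implantation sites before the uterus was taken. Neither the labels nor the design text say whether implantation sites, the tissue between them or the whole uterus was dissociated.

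The authors deposited, for each mouse, a matrix of UMI counts with 32285 genes and the barcodes that had been called cells. The matrices were written by Cell Ranger 6.1.2, per the file headers, and GRCm39 is the genome build named in the submitters' processing notes. The gene annotation is not given in the sources used here. No other step, such as removal of free RNA or of doublets, is recorded in a header or label. Gene symbols were taken from the deposited feature lists, and no coordinates are reported because the genome annotation at hand belongs to another build.

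The 7 matrices held 72108 barcodes, from 8083 to 18653 per library. Cells with at least 200 detected genes and at most 20% of their UMIs from mitochondrially encoded genes were kept, which left 70686. Doublet scores were computed per mouse with the scrublet method in scanpy 1.11.5. Its automatic threshold called between 0 and 4.62% of a library's cells, with 0 cells in control 1, 2 in knockout 2 and 3 in control 3, so the cells with the highest 4% of scores in each mouse were left out instead. That removed 2646 cells and left 68040. Counts were scaled to 10000 UMIs per cell and log transformed. The 2000 most variable genes, 30 principal components and 20 nearest neighbours entered Leiden clustering (leidenalg 0.10.2, resolution 1), which gave 31 clusters.

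Clusters were named from 25 marker lists. A name needed at least 3 detected markers and at least 40% of its list, and 23 clusters received 1 of 15 class names. A final check left out clusters whose 10 leading genes held more markers of another class than of their own. With all other cells pooled as its base, this check left out cluster 8, a cycling stromal-like cluster with the monocyte marker Vcan among its leading genes; with the mean of the other classes as base it would have left out stromal-like cluster 1 instead, because of Il13ra2, a listed luminal marker. The pooled base was adopted after the first outcome had been seen, and both exclusions were run as alternatives. Cluster 8 held 2.96%, 0.418%, 1.86% and 2.46% of the cells of knockouts 1 to 4 and 5.87%, 5.52% and 7.26% of those of controls 1 to 3. In all, 12813 cells stayed unnamed. In control 1 these were 58.7% of the cells, chiefly a single cluster with a median of 1129 UMIs per cell and without a leading class, against 0.915% to 8.94% in the other mice. At resolution 0.5 and 2, the clustering gave 26 and 44 clusters, and 97.3% and 93.2% of cells kept their class. All class names are reconstructions from marker genes, and each means cells like that class.

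UMI counts were summed per mouse and class. A class was tested where at least 3 mice of each genotype had 20 or more of its cells, which held for 12 classes. The sums were fitted with edgeR 4.0.16 (R 4.3.3) after filterByExpr and TMM scaling, by the robust quasi-likelihood test of knockout against control, and p-values were adjusted by the Benjamini-Hochberg method over the genes of a class with a threshold of 0.05. Levels are given as CPM of a class sum with their standard deviation (SD) over mice, and fold changes as log2 of knockout over control with their standard error (SE). Gene lists with at least 5 tested members were tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, adjusted over 384 pairs of list and class. The difference of the genotype effect between stromal and luminal cells was tested with limma on the difference of log2 CPM between both classes of the same mouse, with a prior count of 2. Shares of cells were compared with a two-sided exact permutation test over the 35 splits of the 7 mice into 4 and 3, whose smallest possible p is 0.0286.

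The tests, the samples in them, the marker and gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The doublet threshold, the 40% rule and the other thresholds of naming, the left-out cluster and 18 further alternatives were chosen after seeing the data. Genes named are Lcn2 and Fn1 in every class; the 12 largest rises and falls in stromal, epithelial, macrophage and NK or ILC1 cells, or the 4 largest in other classes, among genes past the threshold with a mean of at least 20 CPM and no overlap between the genotypes; and members of the fixed lists that passed the threshold, or else the members with the highest mean CPM as values.

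The fits were tested on simulated counts with 200 changed genes. For the stromal class (15077 genes), 68.4% of genes changed 2-fold and 88.8% of those changed 4-fold were recovered, with 8 false calls. For the luminal class (7727 genes) the shares were 36.7% and 95.5% with 12 false calls, and for macrophages (6330 genes) 40% and 95.6% with 10. For the difference between stromal and luminal cells (7325 genes), 5.13% of 2-fold and 88.5% of 4-fold changes were recovered with 6 false calls. In the simulated stromal class of 15227 genes, a list raised 2-fold was called at an adjusted p of 7.69e-16 and 0 of the other 40 lists were. That simulation does not show how often camera calls lists falsely in the real counts. There, every split of the mice other than the real one still called from 44 to 115 lists over all classes, against 123 for the real grouping.

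To ask which stromal cells resembled the decidual clusters, each cell of the stromal class was given the nearest of clusters 1, 2, 3, 4, 8 and 9 by its profile over 5198 genes. The profiles came from control cells, and the genes were those above 20 CPM with an absolute log2 ratio under 0.5 between cluster 5 and the other clusters, without mitochondrially encoded genes. This step was chosen after the results were seen. Of the cluster 3 cells themselves, 79.8%, 6.35%, 93.1% and 62.5% in knockouts 1 to 4 were placed nearest cluster 3 or 8. In controls 1 to 3 these shares were 81.7%, 66.1% and 77.9%. The placement thus missed most cluster 3 cells of knockout 2.

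The alternatives covered DESeq2 1.42.0 and its size factors, no filter and a stricter filter on low counts, the mouse number as a block, each mouse left out in turn, doublets kept, other filters on cells, other resolutions, sums thinned to the lowest total, and other set tests and share tests. Those added later left out stromal clusters, genes or droplets with stromal transcripts, and knockout 3 and control 1 together, the libraries with an unusual cell composition and with most of its cells unnamed. Monocyte, ILC2, B, mast, eosinophil, erythroid, trophoblast and Schwann cells received no class, and neutrophils, plasmacytoid dendritic and smooth muscle cells had too few cells to test. The plasmacytoid dendritic cluster had 3 B markers, Cd79a, Cd79b and Ighm, against 4 of its own among its leading genes, so its shares may include B cells. Mx1 and Mx2 of the interferon list are missing from the feature lists.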

Results

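Single-cell transcriptomes were collected from the uteri of 4 mice with a conditional knockout of Lcn2 and 3 control mice with floxed Lcn2 alone, all on day 5 of pregnancy, when mouse embryos attach to the uterine wall. Lcn2 encodes lipocalin 2, a secreted protein that binds siderophores and so takes part in iron transport and in defence against bacteria. The series' title and design text name LCN2, its link to fibronectin (FN1) and the communication of stromal with immune cells during implantation as the subject. The libraries held 90125335, 52836310, 49657399 and 84630639 UMIs in knockouts 1 to 4 and 115544280, 79544573 and 87471571 in controls 1 to 3. After filtering, 68040 cells remained. Their median depth was 8074, 5857, 4492 and 7936 UMIs in the knockouts and 1707, 6795 and 7793 UMIs in the controls. The low value of control 1 went with 10446 unnamed cells of its 17793. Of the 15 named classes, 12 had enough cells to be tested: stromal, luminal and glandular epithelial, vascular and lymphatic endothelial, mesothelial, pericyte, macrophage, dendritic, natural killer or innate lymphoid type 1 (NK or ILC1), T and plasma cells. The stromal class was by far the largest, with 2721 to 5708 cells per mouse, and several others rested on few cells, down to 53 luminal and 22 glandular cells in a mouse.

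The targeted gene was examined first, in every class. In luminal epithelial cells, which line the uterine lumen, Lcn2 stood at 223 ± 47.6 CPM in controls (SD, n = 3) and 0.133 ± 0.195 CPM in knockouts (n = 4). These levels rested on 445 and 2 UMIs, a 1445-fold ratio with an exact 95% interval of 398 to 11970 that covers counting error only. The log2 fold change of -10.02 (SE 0.36) passed edgeR's test (adjusted p = 2.33e-08). Glandular epithelial cells held 48 Lcn2 UMIs in controls, 18.5 ± 7.82 CPM, and 0 in knockouts, at least 28.0-fold lower against a floor of 3 counts over the group (exact permutation p = 0.0286, the smallest possible). The gene was too scarce there for the edgeR fit. Stromal cells had a trace in controls, 0.310 ± 0.126 CPM from 49 UMIs, and 0 UMIs in knockouts, at least 16.7-fold lower by the same floor (edgeR adjusted p = 0.0149). Whether this trace came from stromal cells or from luminal RNA carried into their droplets was not tested. Lymphatic endothelial cells, for which no deletion is stated, carried the highest level of all tested classes in both genotypes, 303 ± 65.4 CPM in controls and 167 ± 73.0 CPM in knockouts, a log2 difference of -0.89 (SE 0.45) that did not pass (edgeR adjusted p = 0.463). Vascular endothelial cells held 19 and 12 UMIs, neutrophils 15 and 10, and macrophages 0 in both genotypes. The luminal call held whichever mouse was left out, whereas the stromal one was lost without control 1 (edgeR adjusted p = 0.0710) and without control 2 (0.0567). The labels do not state which exons are deleted, so a 3' count shows transcript level and not the deletion itself.

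**Figure D1:**
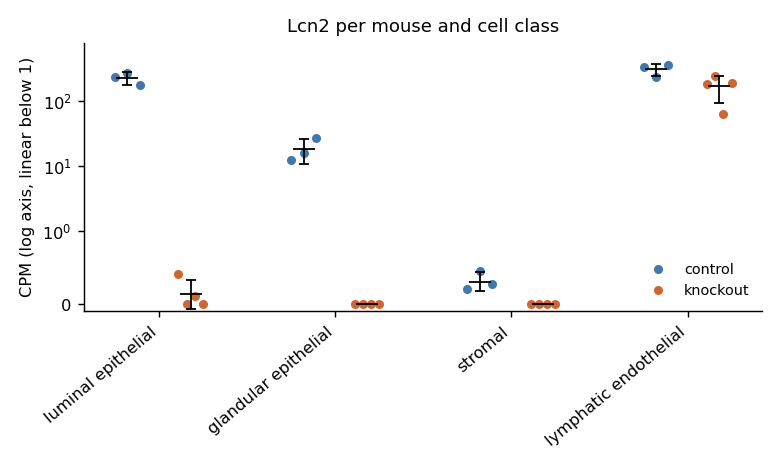
Lcn2 in CPM of each mouse (points; logarithmic axis, linear below 1) by cell class for 3 control and 4 knockout mice, with bars for the mean ± SD. Luminal cells fell from a mean of 223 to 0.133 CPM, while lymphatic endothelial cells held means of 303 and 167 CPM.

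Fn1, which encodes the matrix glycoprotein fibronectin named in the series' title, was most abundant in stromal cells and pericytes among the tested classes and passed the test in none of them. In stromal cells it stood at 697 ± 157 CPM in knockouts (n = 4) and 648 ± 69.2 CPM in controls (n = 3), a log2 fold change of 0.11 (SE 0.18, edgeR adjusted p = 0.698). Pericytes had 665 ± 90.5 and 539 ± 142 CPM (adjusted p = 0.611 in edgeR). Macrophages had 310 ± 108 CPM in knockouts and 447 ± 37.0 CPM in controls, a log2 difference of -0.53 (SE 0.22, edgeR adjusted p = 0.5). Mean levels were also lower in knockout luminal cells, 28.3 ± 13.2 against 85.8 ± 15.9 CPM, and dendritic cells, 33.2 ± 16.9 against 85.7 ± 21.3 CPM, without passing (edgeR adjusted p = 0.152 and 0.267). Both of these classes held fewer droplets with stromal transcripts in knockouts. Droplets with 5 or more UMIs of Col1a1, Col1a2, Col3a1 and Dcn made up 8.57 ± 1.28% of luminal cells in knockouts and 25.7 ± 13.5% in controls. They made up 3.87 ± 1.55% and 7.10 ± 2.66% of dendritic cells. Of 15 tested members of the list of fibronectin and its receptors in stromal cells, 3 rose, with the same 3 adjusted over the list alone, and 0 fell: the integrin subunits Itgb8 (log2 fold change 0.80), Itga8 (0.75) and Itgb3 (0.59). The list as a whole did not move (median 0.00, camera in limma, adjusted p = 0.742).

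**Figure D2:**
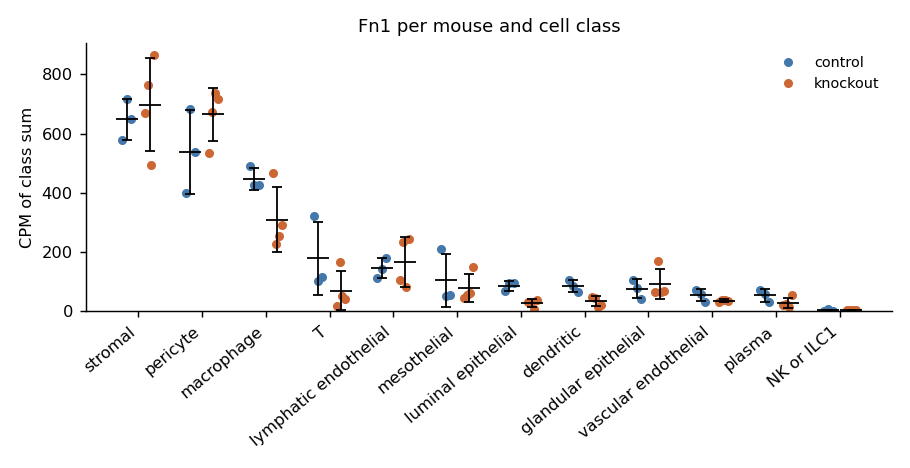
Fn1 in CPM of each mouse (points) by tested cell class for 3 control and 4 knockout mice, with bars for the mean ± SD. Stromal means of 648 and 697 CPM overlap within their spread, and the lower knockout means of luminal (28.3 CPM) and dendritic cells (33.2 CPM) did not pass the test.

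Stromal cells, the fibroblast-like cells that form the decidua, were the class with the most cells and UMIs. Of 15227 genes tested, 1275 rose and 1793 fell in knockouts (3068 in all by edgeR, 5751 at an unadjusted p under 0.05, 4091 by DESeq2). The genes that fell most included Cthrc1, a secreted protein of remodelling matrix, at 25.6 ± 16.1 CPM in knockouts (n = 4) and 127 ± 24.9 CPM in controls (n = 3), a log2 fold change of -2.31 (SE 0.65). The neutrophil-attracting chemokines Cxcl2 (28.4 ± 18.0 against 132 ± 1.17 CPM) and Cxcl1 (87.0 ± 36.5 against 308 ± 11.2 CPM) fell, as did the soluble pattern receptor Ptx3 (27.0 ± 16.4 against 118 ± 44.1 CPM) and the metal-binding metallothionein Mt2 (107 ± 29.0 against 363 ± 114 CPM). Rises were led by Timp3, an inhibitor of matrix proteases (149 ± 78.2 against 46.4 ± 13.2 CPM, log2 fold change 1.68, SE 0.39), and the methyltransferase Inmt (154 ± 87.6 against 52.4 ± 11.7 CPM). The endothelin receptor Ednrb and the relaxin receptor Rxfp1 rose by log2 fold changes of 1.42 and 1.32. Rises were also seen in Tsc22d3 (135 ± 45.3 against 56.4 ± 6.98 CPM) and Txnip (205 ± 49.2 against 86.3 ± 6.81 CPM), which respond to glucocorticoids and to glucose. Axin2, a target of Wnt signalling, rose by a log2 fold change of 1.21, and Pamr1, Mylip, Fbxo32, Cpe and Aox3 were the other large rises, at 1.65, 1.33, 1.30, 1.23 and 1.21.

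Among the stromal genes of the cell cycle, 17 of 20 S phase genes fell and none rose (19 fell adjusted over the list alone; median log2 fold change -1.06, camera adjusted p = 6.53e-08). They included thymidylate synthase Tyms (-1.51) and the replication factors Clspn (-1.51) and Gins2 (-1.45). Of the 20 G2M genes 4 fell, all 20 adjusted over the list alone (median -1.68, camera adjusted p = 2.64e-07), among them the mitotic kinase Cdk1 (19.0 ± 10.1 against 62.6 ± 12.1 CPM) and its partner Ccna2 (11.2 ± 7.44 against 42.7 ± 7.12 CPM). Cholesterol synthesis genes fell together, 13 of 18 (15 adjusted over the list alone; median -0.81, camera adjusted p = 1.17e-07), with Fdps at -1.48, Cyp51 at -1.30 and the lipoprotein receptor Ldlr at -1.13. Of 20 oxidative phosphorylation genes 13 fell (16 adjusted over the list alone; median -0.43, camera adjusted p = 1.22e-06), such as Uqcrq (-0.86) and Cox5a (-0.70). The 13 mitochondrially encoded genes, whose share also follows the quality of cells, went the other way as a list (0 rose and 1 fell, mt-Nd3 at -1.75; 4 rose and 1 fell adjusted over the list alone; median 0.30, camera adjusted p = 0.0341). That call was lost without control 1, control 2, knockout 2 or knockout 4 and had an adjusted p = 0.631 with an estimated correlation. Of 18 genes of hypoxia and glycolysis 9 fell and 2 rose (10 and 3 adjusted over the list alone; median -0.64, camera adjusted p = 0.0101), with the glycolytic enzymes Eno1, Ldha and Hk2 at -1.08, -1.07 and -1.06. The S phase, G2M, cholesterol, oxidative phosphorylation and glycolysis lists each lost their call with an estimated correlation (adjusted p = 0.631 with an estimated correlation, limma).

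Matrix and inflammatory lists also moved in stromal cells. Of 25 collagen and matrix genes 4 fell and 1 rose, with the same counts adjusted over the list alone (median -0.36, camera adjusted p = 0.0101); periostin (Postn) fell by 1.48 on the log2 scale and Col15a1 rose by 0.53. That call was lost with an estimated correlation (adjusted p = 0.670 with an estimated correlation, limma), without control 2 and without knockout 1. Of 18 NF-kB targets 3 fell, also 3 adjusted over the list alone (median -0.53, camera adjusted p = 0.00234), Cxcl1, Tnfaip2 (-1.16) and Sod2 (-0.65). Of 14 genes of endoplasmic reticulum stress 6 fell, among them Sdf2l1 (-1.32) and Calr (-0.75; 8 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.0470, lost without control 1, knockout 1 or knockout 3). Of 17 genes of ferroptosis and oxidative defence 5 fell and 2 rose (7 and 2 adjusted over the list alone; camera adjusted p = 0.0428, lost without control 2, control 3, knockout 2 or knockout 3). Both of these and the NF-kB list stood at an adjusted p = 0.631 with an estimated correlation. Decidualization genes went both ways, 7 of 29 up and 7 down (11 and 9 adjusted over the list alone): the alkaline phosphatase Alpl (-2.31) and the progesterone-induced chaperone Fkbp5 (-0.97) fell, while Hbegf (0.99) and the hedgehog receptor Ptch1 (0.77) rose. That list's median was 0.26 and its mean -0.05, and it did not pass (camera, limma, direction up, adjusted p = 0.706). The progesterone receptor Pgr and Hoxa10, markers of the stroma, rose by 0.43 and 0.42. The epithelial tight junction genes Cldn3, Cldn1 and Cldn10 rose by 2.06, 1.20 and 1.09 from 1.68, 7.13 and 11.8 CPM in controls, while luminal cells, which also express epithelial genes, made up 3.15 ± 3.86% of knockout cells (8.89% in knockout 3 and 0.665 to 1.93% in the others) and 0.634 ± 0.318% of control cells. The barrier list held 4 rises among 12 genes (5 adjusted over the list alone; camera adjusted p = 0.0426, lost without control 2 or any of knockouts 1 to 3, and an adjusted p = 0.631 with an estimated correlation).

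**Figure D3:**
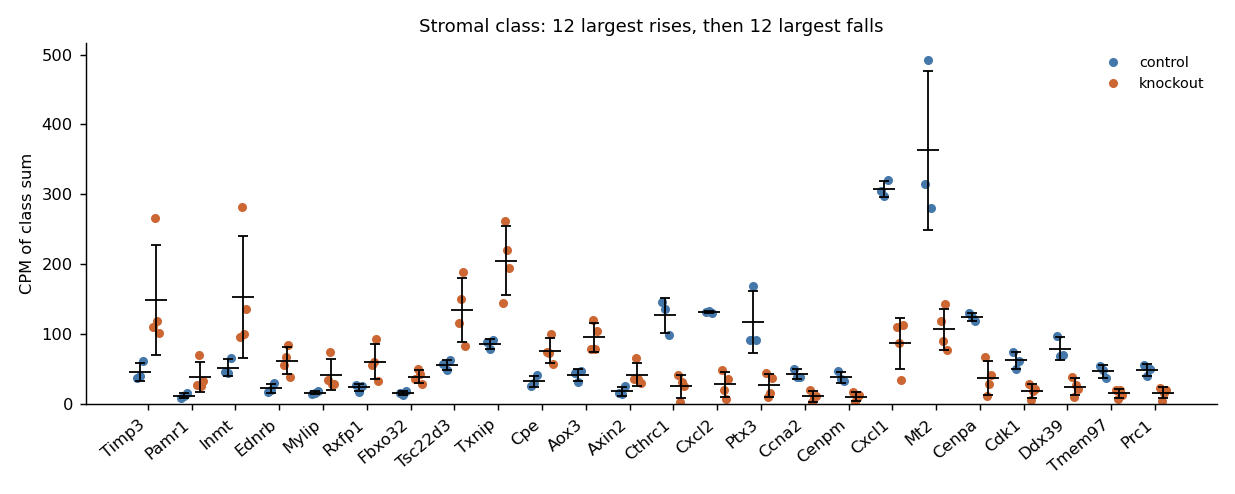
The 12 largest rises and the 12 largest falls in stromal cells, as CPM of each mouse (points, linear axis) for 3 control and 4 knockout mice, with bars for the mean ± SD. Cthrc1 had means of 25.6 CPM in knockouts and 127 CPM in controls, and Timp3 149 and 46.4 CPM.

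The stromal class was made of different clusters in the 2 genotypes. Cluster 3 was led by Ptx3, Cthrc1, Wnt4 and Tdo2, with the G2M gene Ube2c also among its leading genes. It was the most decidual of the class by its markers, at a score of 0.563 against 0.490 for cluster 9. Where clusters 3 and 8 are called decidual, the name rests on this score, and both also had cell cycle genes among their leaders. Cluster 3 held 388, 63, 58 and 294 cells in knockouts 1 to 4 and 1737, 1650 and 1232 in controls 1 to 3. Clusters 1 and 2, led by Il13ra2, Rxfp1 and Ednrb and by Inmt, were the largest among knockout cells. Without cluster 3, 0 genes passed in edgeR, with 1693 of the 3032 class changes tested again still at an unadjusted p under 0.05 and their median log2 fold change in the class's direction at 0.33 (SE 0.13) in place of 0.62 (SE 0.14). The calls also needed both controls 1 and 2: 0 genes passed without either (lowest adjusted p of edgeR 0.0710 and 0.0567, with 3027 and 3067 of the 3068 at an unadjusted p under 0.05 and median fold changes of 0.58 and 0.61; DESeq2 was not run there), against 2033 without control 3 and 2045 without knockout 4.

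In luminal epithelial cells 12 genes rose and 48 fell of 7988 tested (60 in all by edgeR, 1098 at an unadjusted p under 0.05, 213 by DESeq2). Keratin 19 (Krt19) rose from 193 ± 8.47 CPM in controls (n = 3) to 467 ± 51.5 CPM in knockouts (n = 4), a log2 fold change of 1.28 (SE 0.16). The plasma membrane calcium pump Atp2b2 (83.8 ± 22.3 against 23.2 ± 5.27 CPM), the calcium-binding protein Calb1 (411 ± 98.5 against 170 ± 36.3 CPM), the zinc and iron importer Slc39a14 (62.3 ± 5.54 against 26.6 ± 3.27 CPM) and Clic5 (log2 fold change 2.09) rose too. Besides Lcn2, the falls included the lipid enzymes Fads3 (3.37 ± 2.22 against 45.8 ± 17.6 CPM, log2 fold change -3.40, SE 0.38), Pla2g7 (-3.26) and Degs2 (7.75 ± 2.15 against 51.6 ± 19.2 CPM). The hormone-responsive kinase Sgk1 (48.8 ± 5.90 against 174 ± 47.7 CPM) fell. Id1 and Id3, transcriptional regulators induced by BMP signalling, fell too (Id3 104 ± 16.5 against 339 ± 88.9 CPM). The iron storage gene Fth1 fell by 0.90 on the log2 scale, the claudin Cldn10 by 1.16 and Wnt7b by 1.12.

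Of the luminal lists, hypoxia and glycolysis had 0 of 15 members past the threshold over all genes and 12 lower adjusted over the list alone (median log2 fold change -0.84, camera adjusted p = 1.28e-07, adjusted p = 0.631 with an estimated correlation). Cytosolic ribosomal protein genes, which also follow RNA quality, were lower as a list (0 of 20 changed over all genes and adjusted over the list alone; median -0.20, camera adjusted p = 0.00179, adjusted p = 0.668 with an estimated correlation). The list of Lcn2 and iron handling, which holds the deleted gene itself, had a median of 0.09 and, with Lcn2 included, a mean of -0.83 over 11 genes, with 1 rise and 2 falls, of Lcn2 and Fth1 (1 and 3 adjusted over the list alone), and did not pass camera in limma (direction down, adjusted p = 0.161). Collagen and matrix genes formed the list with the lowest p: 6 of 20 fell, 19 adjusted over the list alone (median -2.15, camera adjusted p = 2.81e-21, adjusted p = 0.631 with an estimated correlation), among them Col3a1 (-2.54), Col1a2 (-2.49) and Lum (-2.64). Of 9 stromal markers 3 fell with them (6 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.000189, also 0.631 with an estimated correlation). These are genes of stromal cells, and the droplets with stromal transcripts described for Fn1 moved with them. Without those droplets 52 genes changed in luminal cells by edgeR, 32 of them among the 60, and 3 were genes more than 3 times higher in stromal cells. Lcn2, Krt19, Fads3, Degs2, Col6a3, Lum, Selenom, Sgk1, Id3 and Igfbp4 passed whichever mouse was left out, but Col6a3, Lum, Selenom and Igfbp4 were among the genes without a test once those droplets were left out. Calb1 and Clic5 lost their call without them (edgeR adjusted p = 0.0819 and 0.0592) and without control 1, 2 or 3 or knockout 1 or 3. The count was 37, 31 and 20 without controls 1 to 3 and 20, 97, 31 and 151 without knockouts 1 to 4. In glandular epithelial cells edgeR called 0 of 7456 genes, with 318 at an unadjusted p under 0.05 and 2 by DESeq2, on 22 to 207 cells per mouse.

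The immune environment was the question named in the design text. Macrophages changed in 8 of 6649 genes, 3 up and 5 down (edgeR; 571 at an unadjusted p under 0.05, 24 by DESeq2). Lyve1, a hyaluronan receptor of tissue-resident macrophages, fell from 50.4 ± 22.9 CPM in controls (n = 3) to 5.18 ± 0.643 CPM in knockouts (n = 4), a log2 fold change of -3.28 (SE 0.38, edgeR adjusted p = 0.00170). It passed whichever mouse was left out, but not without knockout 3 and control 1 together (log2 fold change -3.39, edgeR adjusted p = 0.0911). Lyve1 is also a listed marker of lymphatic endothelial cells and was among the leading genes of their cluster. Whether lymphatic RNA in macrophage droplets carried part of its level was not tested. The cholesterol exporter Abcg1 rose (135 ± 13.7 against 53.1 ± 9.14 CPM), as did AU020206 and the junction protein F11r (log2 fold changes 1.67 and 1.47), and the opioid precursor Penk (-1.96) and Ppp1r14b (-1.10) fell. Of the 5 falls, 2 were genes with over 3 times the CPM in stromal cells, Penk among them at 144 CPM there, and without droplets with stromal transcripts 2 genes changed in macrophages. The list of tissue-resident and alternatively activated macrophages had 1 fall among 12 genes, that of Lyve1, also 1 adjusted over the list alone, and a median of -0.16 (camera adjusted p = 0.0478, lost without control 2, control 3, knockout 1, knockout 3 or knockout 4, and adjusted p = 0.631 with an estimated correlation). Genes of antigen presentation on MHC class II leaned higher: 9 of 10 were higher adjusted over the list alone and 0 over all genes (median 0.81, camera adjusted p = 1.68e-10, adjusted p = 0.631 with an estimated correlation), with H2-Aa at 7367 ± 1388 against 4198 ± 997 CPM. In that class 2 genes changed without control 1, control 2 or knockout 4, 5 without control 3 and 16 without knockout 2. Droplets with stromal transcripts made up 5.07 ± 3.34% of it in knockouts and 7.56 ± 6.53% in controls.

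NK or ILC1 cells showed 0 changed genes of 9903 and T cells 0 of 7193 in edgeR, with 1413 and 388 at an unadjusted p under 0.05 and 5 and 16 by DESeq2. The NK list of cytotoxicity and maturation did not pass, with 0 of 20 genes changed over all genes and adjusted over the list alone (median 0.18, camera in limma, adjusted p = 0.540). Dendritic cells had 4 rises and 49 falls of 8536 genes (edgeR; 933 at an unadjusted p under 0.05, 102 by DESeq2). The list of immediate early genes and dissociation stress was higher in them (0 of 23 changed over all genes, 4 higher adjusted over the list alone; camera adjusted p = 0.00551, lost without control 2 or knockout 1, and adjusted p = 0.631 with an estimated correlation). It was also higher in NK or ILC1 cells (0 and 3 of 23; camera adjusted p = 0.00516, lost without control 2 or knockout 2, and adjusted p = 0.670 with an estimated correlation). The interferon-induced chemokine Cxcl9 rose from 25.2 ± 11.6 to 93.8 ± 19.1 CPM, a log2 fold change of 1.84 (SE 0.28), and the fatty acid receptor Ffar4, the adhesion molecule Cadm1 and the lysosomal enzyme Ppt1 rose by 0.91, 0.82 and 0.63. Of its falls, 39 were genes with over 3 times the CPM in stromal cells, such as Postn (-4.19), Col4a1 (-1.90) and Mt2 (-2.82), and without the droplets with stromal transcripts only Fdps, an enzyme of cholesterol synthesis, stayed past the threshold. The dendritic count was 0 without control 1, 4 without control 2, 98 without control 3, 91 without knockout 2 and 20 without knockout 3. Plasma cells changed in 1 gene, Cxcl1 (4.10 ± 2.13 against 47.7 ± 10.8 CPM), which is also a stromal transcript and no longer passed without those droplets.

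Across classes, 123 of 384 tests of a list in a class passed camera in limma, 31 up and 92 down, and 0 did with an estimated correlation (lowest adjusted p = 0.631 with an estimated correlation); fry called 3. The 31 lists higher in knockouts were 15 without control 1 and 18 without knockout 4. The interferon response list was higher in knockouts in 10 of the 12 classes, with medians from 0.41 to 0.89, although a single member passed the threshold in any class, Ifit3 in stromal cells (log2 fold change 1.30). In NK or ILC1 cells 0 of its 18 members passed over all genes, and 10 were higher and 1 lower adjusted over the list alone (camera adjusted p = 1.25e-06, adjusted p = 0.631 with an estimated correlation). The number of classes fell to 5 without knockout 4 and to 6 without control 1. S phase genes and cholesterol synthesis genes were each lower in 8 classes, collagen and matrix genes in 10, and class I presentation genes higher in 6 (camera; all at or above an adjusted p = 0.631 with an estimated correlation). Lists of stromal markers were lower in 6 classes, dendritic, luminal, macrophage, plasma, T and vascular endothelial cells. The summed CPM of Col1a1, Col1a2, Col3a1 and Dcn stood at 8.20 ± 5.82% of the stromal level in knockout and 28.3 ± 21.9% in control T cells, 2.51 ± 1.18% and 7.15 ± 4.08% in vascular endothelial cells, 4.96 ± 2.16% and 9.22 ± 2.63% in plasma cells, and 9.84 ± 5.56% and 14.1 ± 6.65% in macrophages. In lymphatic endothelial cells the collagen list's median was 0.03 while its test went down.

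**Figure D4:**
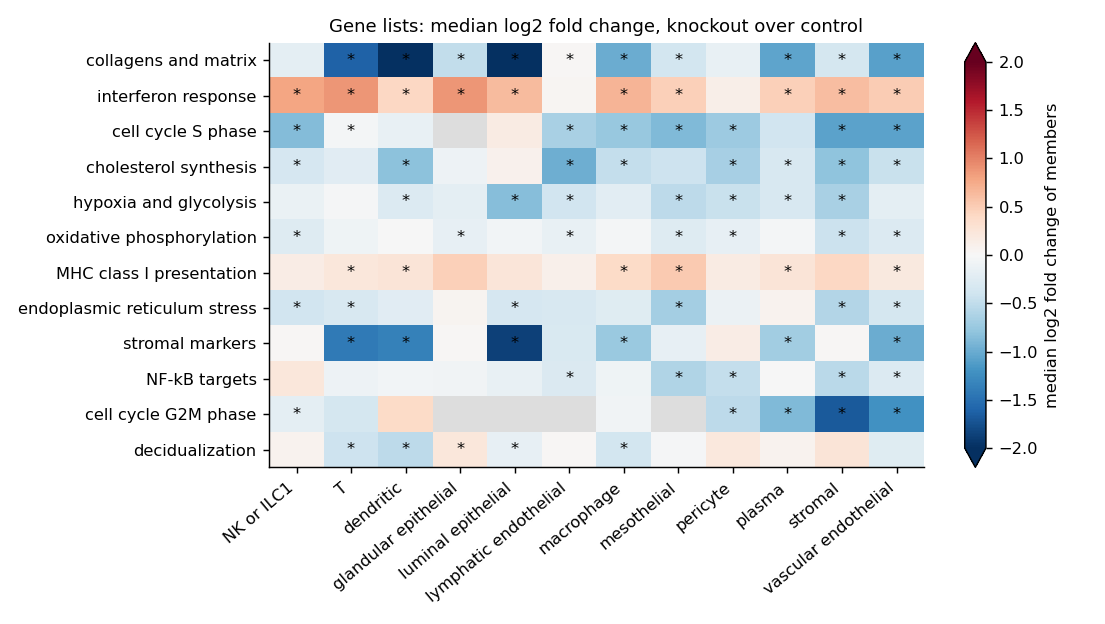
Median log2 fold change, knockout over control, of the tested members of 12 gene lists (vertical) in 12 cell classes (horizontal), from 4 knockout and 3 control mice; stars mark an adjusted p under 0.05 by camera and gray cells had under 5 tested members. The interferon list carried medians of 0.41 to 0.89 in the 10 classes where it was called, and S phase genes reached -1.06 in stromal cells.

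Whether the genotype effect differed between the stromal and luminal classes was tested on the within-mouse difference of their levels. Of 7741 genes, 9 differed in limma, 7 with the effect more positive in stromal cells and 2 more positive in luminal cells (1519 at an unadjusted p under 0.05). Lcn2 led, with a difference of 4.72 (SE 0.38, limma adjusted p = 0.00210), a size that depends on the prior count because stromal cells were near 0. Fads3 (2.96), Id1 (2.23), Cldn10 (2.24), Fbxo32 (1.92), Sorcs2 (1.84) and Ly6g6c (3.68) had the more positive effect in stromal cells. Slc39a14 (-1.61) and Tnfaip3, an inhibitor of NF-kB signalling (-1.60), had it in luminal cells. Cldn10 fell in luminal cells (-1.16) and rose in stromal cells (1.09). Of these genes, Lcn2 alone was called in all 7 fits with 1 mouse left out. Sorcs2 was called in 5 of them, Fbxo32 in 4, Fads3 and Id1 in 3, Ly6g6c and Tnfaip3 in 2, and Cldn10 and Slc39a14 in 1. Without controls 1 to 3 the count was 2, 2 and 3, and without knockout 4 it was 18. With a mean of at least 20 CPM in both classes it was 113, 54 more positive in stromal and 59 in luminal cells, and the 3 of the 9 that were still tested were all called. Without the droplets with stromal transcripts it was 27, 9 of them shared.

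The other classes were tested in the same way. Mesothelial cells of the outer surface had 66 rises and 132 falls of 8665 genes (edgeR; 1494 at an unadjusted p under 0.05, 171 by DESeq2). Ferroportin (Slc40a1), the cellular iron exporter, rose from 14.8 ± 3.40 to 49.6 ± 9.31 CPM and Rab17 by a log2 fold change of 1.80. The hyaluronan synthase Has1 (-2.13), the protease inhibitor Timp1 (-1.80), Cxcl2 (-3.21) and the glycolytic enzymes Eno1 (-0.87) and Ldha (-1.29) fell. In the same cells the list of immediate early genes and dissociation stress, a sign of handling, was lower (0 of 23 changed over all genes and adjusted over the list alone; median -0.37, camera adjusted p = 0.00215, lost without control 1 or knockout 2, and adjusted p = 0.678 with an estimated correlation). So were 20 cytosolic ribosomal protein genes as a list (0 changed either way; median -0.17, camera adjusted p = 0.0281, lost without control 1 or knockout 4, and adjusted p = 0.700 with an estimated correlation). Lymphatic endothelial cells changed in 81 of 7673 genes, 25 up and 56 down (edgeR; 1051 at an unadjusted p under 0.05, 90 by DESeq2). There the growth factor-induced genes Ccn2 (29.1 ± 7.29 against 102 ± 8.48 CPM) and Ccnd1 (178 ± 35.3 against 466 ± 99.8 CPM), the matrix protein Tnc (-1.60) and the epithelial cytokine Tslp (-2.30) fell, and the selenium carrier Selenop rose (1.07). The ribosomal list was lower in lymphatic cells too (camera adjusted p = 0.0316, lost without knockout 3, control 2 or control 3, and not called with an estimated correlation). Pericytes changed in 2 genes, Pln (2.11) and the calcium-binding S100a6 (-1.24), of 8081 (edgeR; 798 at an unadjusted p under 0.05, 25 by DESeq2). S100a6 stood at 3424 CPM in stromal cells, and without genes 3 times higher there edgeR called 0 in pericytes. Pln is not such a gene. It lost its call in the new adjustment, at the same log2 fold change of 2.11. Their handling stress list was lower as well (median -0.43, 0 of 23 changed over all genes and adjusted over the list alone, camera adjusted p = 7.63e-05, lost without knockout 3, and adjusted p = 0.644 with an estimated correlation), and so was the ribosomal list (median -0.21, 0 of 20 changed either way, camera adjusted p = 0.00197, and adjusted p = 0.631 with an estimated correlation). In vascular endothelial cells edgeR called 1 of 10908 genes, the kinase Prkg1, against 2335 at an unadjusted p under 0.05 and 382 by DESeq2. The mesothelial count was 106 and 70 without controls 1 and 2 and 68, 89 and 99 without knockouts 1 to 3. The lymphatic count was 33 and 8 without controls 1 and 2, 35, 18 and 24 without knockouts 1 to 3 and 157 without knockout 4. The pericyte count reached 13 without knockout 1, and the vascular one 493 without knockout 1, 126 without knockout 2 and 42 without control 3.

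Cells were also counted by class. No share passed its test, but with 35 splits of the mice and 15 classes a single class that separated the genotypes fully would only reach an adjusted p of 0.429. Over the 15 named classes the lowest exact permutation p was 0.286 (adjusted p 0.827). Stromal cells made up 58.8 ± 16.2% of the cells in knockouts (n = 4) and 48.9 ± 17.7% in controls (n = 3), but 60.5 ± 16.4% and 66.2 ± 8.52% of the named cells. Luminal cells made up 3.15 ± 3.86% and 0.634 ± 0.318%, a difference of 2.52 points that was 0.601 without knockout 3. Among immune cells, NK or ILC1 cells made up 32.8 ± 15.9% in knockouts and 27.7 ± 10.2% in controls, dendritic cells 23.2 ± 16.3% and 19.6 ± 1.24%, T cells 19.3 ± 4.60% and 18.8 ± 6.77%, and macrophages 16.5 ± 5.50% and 19.9 ± 6.60%. Plasma cells had the lowest p of these, 6.38 ± 3.13% against 12.1 ± 2.36% (exact permutation p = 0.0857, adjusted p = 0.600). Shares of all cells moved with the 58.7% of unnamed cells in control 1. With named cells alone as the denominator, plasma cells made up 1.35% in knockouts and 2.64% in controls without overlap between the mice (exact permutation p = 0.0286, adjusted p = 0.429).

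**Figure D5:**
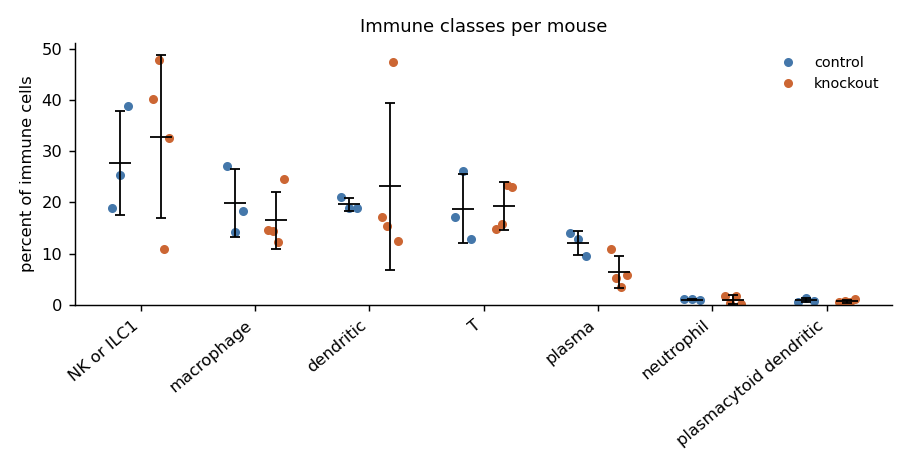
Share of each immune class among the immune cells of a mouse in percent (points), for 3 control and 4 knockout mice, with bars for the mean ± SD. NK or ILC1 cells had means of 27.7% and 32.8% and macrophages 19.9% and 16.5% in controls and knockouts, and knockout 3 stood apart in its dendritic share of 47.4%.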

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

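The tests of droplets, of stromal clusters and nearest clusters, of cycling cells and of leaving out the genes of stromal cells were chosen after the results they examine had been seen. Of 119 groups of 4 mice examined, 13 held a mouse far from the other 3, and chance alone marks about 1 group in 20. Knockout 3 had the highest share of dendritic cells (14.7% of kept cells, against 2.33 to 3.58% in the other knockouts, and 47.4% of immune cells), of luminal cells (8.89%) and of lymphatic endothelial cells (3.84%). Fn1 reached 169 CPM in glandular cells of knockout 2 and 150 CPM in mesothelial cells of knockout 4. Knockout 4 had the highest knockout levels of the stromal transcripts Lum (9.85 CPM), Col3a1 (104 CPM), Col1a2 (68.9 CPM) and Rcn3 (17.5 CPM) in luminal cells. In stromal cells knockout 2 stood above the other knockouts in Timp3 (266 CPM), Mylip (75.0 CPM) and Axin2 (66.8 CPM).

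The genotype effect differed between stromal and luminal cells by limma's test of the difference in 9 genes: Lcn2 (4.72), Ly6g6c (3.68), Fads3 (2.96), Cldn10 (2.24), Id1 (2.23), Fbxo32 (1.92), Sorcs2 (1.84), Slc39a14 (-1.61) and Tnfaip3 (-1.60). Without controls 1 to 3 there were 2, 2 and 3 such genes, and without knockout 4 there were 18. Lcn2 alone was called in all 7 fits with 1 mouse left out. The real grouping gave the most of the 35 splits of the 7 mice, 9 genes against a highest other value of 1. For this count taken alone that is an exact permutation p of 0.0286. With no adjustment for the 14 counts examined, chance is not excluded. Without knockout 3 and control 1 together limma called 0 genes.

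Genes of stromal cells made up much of what was lower in knockout dendritic and luminal cells. Free RNA spread evenly over all droplets is argued against as the main source of the UMIs of 4 stromal genes in these cells. In every mouse at least 90.6% of them in dendritic cells and 65.3% in luminal cells sat in the tenth of cells with the most. Poisson draws with a single mean for all cells of a mouse gave at most 33.1% and 22.6%. Such draws leave out the spread of depth between cells. A smaller part from free RNA is not excluded, and where the genotype difference arose is not shown. Without droplets with 5 or more such UMIs, 51.6% of 281 stromal-rich genes were lower in dendritic cells and 49.5% of 109 in luminal cells, against 77.9% and 78.0% of the same genes with all cells. Leaving out these droplets, 7.10% of control and 3.87% of knockout dendritic cells and 25.7% and 8.57% of luminal cells, trims the difference itself, so droplets that also held a stromal cell and a change in the dendritic or luminal cells cannot be told apart. Without them 52 genes were called in luminal cells and 1 in dendritic cells.

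The stromal changes went with fewer cells of the decidual kind in knockouts: without cluster 3, 0% of the 3068 genes stayed past edgeR's threshold and 99.5% of the 3032 tested again kept their direction, while the median fold change went from 0.62 (SE 0.14) to 0.33 (SE 0.13), so the call ended because the folds shrank at a similar error. Fitted alone, cluster 9 had 4 changed genes in edgeR and clusters 1, 2, 3 and 4 had 0. In clusters 1 to 4 the class changes had median fold changes of 0.17, 0.13, 0.12 and 0.07 (SE 0.14, 0.14, 0.22 and 0.17). The median was 0.44 in cluster 9 (SE 0.25) and 0.64 in cluster 5 (SE 0.18), where 62.9% of the class changes were called. In cluster 5 this was 0% once the cells nearest the decidual clusters 3 and 8 were left out (edgeR, 1230 of 11009 genes at an unadjusted p under 0.05, DESeq2 not run). Those cells were 31.4 ± 3.76% of its control and 4.83 ± 4.00% of its knockout cells (exact permutation p = 0.0286). This p does not stand as a test: the profiles came from control cells of the real grouping and were not rebuilt for each split. However, 83.9% of the genes kept their direction in cluster 5 without those cells (median fold change 0.21, SE 0.18), and 93.7% in the whole class without such cells (0.23, SE 0.13). Since these genes were picked as changed in the same mice, kept directions are no independent support, and no share for other genes is given. A lower share of decidual cells could thus account for a part, but whether it is the whole cause cannot be told apart from a change in all stromal cells, which would also move the cluster a cell lies nearest, and a different mix of implantation sites and the tissue between them, which the labels do not state, was not tested. With the sums thinned to the lowest total, 79.7% of genes were still called, narrowly short of the bound of 80 set in advance against depth. The fold ratio, a measure chosen afterwards, was 0.985, but thinning keeps each gene's expected share, so this ratio would barely move whatever the cause. Thinning of sums also leaves the depth per cell as it was, so depth stays undecided. Fewer cycling cells cannot be told apart either. Of the 2855 class changes outside the cycle lists tested in cluster 2, 76.8% kept their direction and 0 were called. The S phase median was -0.15, -0.22, -0.08 and -0.30 in clusters 1 to 4, less far below 0 than in the class as a whole. In clusters 5 and 9 it was -1.10 and -0.81.

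The interferon response list was higher in 10 knockout classes by camera, and in 0 with an estimated correlation (lowest adjusted p = 0.631 with an estimated correlation, limma). Without knockout 4 there were 5, exactly at the bound set in advance for a single mouse as the source, and 6 without control 1, so this explanation stays open. The mean of the list over the 12 classes was -0.0364, 0.281, 0.0186 and 0.585 in knockouts 1 to 4 and 0.21 ± 0.28 against -0.28 ± 0.18 in controls (exact permutation p = 0.0571), and in stromal cells knockout 4 stood at 1.19 and the other knockouts at -0.0872, 0.0475 and -0.270. Without the genes 3 times higher in stromal cells, with none left out in the stromal class itself, the list was still called higher in 8 classes. List members below that ratio stayed in and can carry free RNA too, so this does not decide on free RNA from stromal cells. Whether the genotype or another difference between these mice lies behind the list was not tested.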

How the results depend on the processing

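The settings that left out stromal clusters, stromal-rich genes, droplets with stromal transcripts, or knockout 3 and control 1 together, and that took named cells as the denominator, were chosen after seeing the data. The cause of a change in a count was not tested, except that a mouse left out or a stricter filter leaves fewer mice or genes. Changed genes were, with DESeq2, dendritic 102, glandular 2, luminal 213, macrophage 24, NK or ILC1 5, pericyte 25, plasma 31, T 16 and vascular 382. With no filter on low counts they were dendritic 401, glandular 54, luminal 298, lymphatic 267, macrophage 94, mesothelial 462, NK or ILC1 9, pericyte 124, plasma 168, T 171 and vascular 643. A mean of at least 20 CPM gave dendritic 13, luminal 35, macrophage 5, plasma 2, stromal 1887 and vascular 0, and 113 genes for the difference between stromal and luminal cells. Keeping doublets gave dendritic 117, lymphatic 28, macrophage 21, mesothelial 479, pericyte 0, plasma 2, T 62 and vascular 84. Resolution 0.5 gave glandular 1, plasma 2 and vascular 0. Thinning to the lowest total gave dendritic 19, lymphatic 53, macrophage 2, mesothelial 128, pericyte 1 and vascular 154.

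Without knockout 3 and control 1 the counts were dendritic 0, luminal 36, lymphatic 18, macrophage 0, mesothelial 83, pericyte 0, plasma 3, stromal 0 and vascular 2, with 79 lists and 0 genes of the difference, and the fitted Lcn2 value in stromal cells, -7.17, did not pass. Without stromal-rich genes they were dendritic 0, luminal 20, macrophage 5, pericyte 0 and plasma 0. Without droplets with stromal transcripts they were dendritic 1, macrophage 2 and plasma 0, with 27 genes of the difference, and without cluster 3 stromal 0. An estimated correlation left 0 lists, and fry called 3, of which 1 was called by camera in the same direction.

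The mouse numbers are not stated to pair the mice, and in no class did all 3 pairs of equal number correlate above 0.1 (stromal 0.312, 0.280 and -0.103). With the replicate block the counts were dendritic 227, glandular 8, luminal 202, lymphatic 141, macrophage 4, mesothelial 326, NK or ILC1 65, pericyte 7, plasma 41 and vascular 8, and 18 lists were higher in knockouts.

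With 1 mouse left out in turn, counts ranged over dendritic 0 to 98, glandular 0 to 2, luminal 20 to 151, lymphatic 8 to 157, macrophage 2 to 16, mesothelial 68 to 225, NK or ILC1 0 to 0, pericyte 1 to 13, plasma 2 to 18, stromal 0 to 2822, T 0 to 7 and vascular 0 to 493, lists 84 to 133 and the difference 2 to 18. Lcn2 ranged from -10.49 to -9.35 in luminal, -1.09 to -0.59 in lymphatic and -7.00 to -6.49 in stromal cells. The stromal values are the fit's own over 0 knockout UMIs, so they give no size beyond the bound of at least 16.7-fold. Differences of shares of all cells in percentage points ranged over NK or ILC1 -0.670 to 2.65, T -0.463 to 3.04, dendritic -0.557 to 3.59, macrophage -0.273 to 1.47, neutrophil -0.0561 to 0.132, plasma -1.46 to 0.0917 and plasmacytoid dendritic -0.0981 to 0.0866. Of immune cells they ranged over T -2.39 to 4.25, dendritic -4.54 to 7.11, macrophage -6.23 to 0.221, neutrophil -0.238 to 0.268 and plasmacytoid dendritic -0.324 to 0.0443. NK or ILC1 cells, at 0.219 to 12.5, and plasma cells, at -7.21 to -4.75, kept their direction there.

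Shares that turned direction, none past its test, were plasmacytoid dendritic (0.198 with logit shares, 0.00347 with at least 500 genes), macrophage (-0.0598 with edgeR and the block, -0.0185 of named cells) and, of named cells, glandular -0.0515, pericyte -0.0279 and stromal -5.69. Without knockout 3 and control 1 the turned shares were T -1.34, dendritic -1.65, lymphatic -0.197, mesothelial -0.0169 and neutrophil -0.123, and of immune cells T -1.61, dendritic -3.82, macrophage 1.60 and neutrophil -0.224. Immune neutrophil shares also turned with logit shares (-0.286) and edgeR (-0.00588), and T with the block (-0.0293).

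Fn1, called nowhere, turned direction in glandular cells (-0.18 at resolution 0.5), lymphatic cells (-0.17 with the block), mesothelial cells (0.58 without knockout 3 and control 1), NK or ILC1 cells (-2.27 at resolution 0.5, -0.0512 without knockout 3 and control 1), stromal cells (-0.0320 with the block) and vascular cells (0.32 without droplets with stromal transcripts). With 1 mouse left out it ranged over glandular -0.23 to 0.71, lymphatic -0.12 to 0.41, mesothelial -0.87 to 0.49, NK or ILC1 -0.33 to 0.97 and stromal -0.0172 to 0.239. Col4a1 in dendritic cells turned to 0.17 without such droplets. Lists turned in pericytes (immediate early genes 0.0154) and T cells (MHC class II -0.25, NK markers -0.0446) without knockout 3 and control 1, and in T cells without droplets with stromal transcripts (MHC class I -0.0177, S phase 0.0810). These list values are the mean log2 fold change of the members less that of all genes. With 1 mouse left out they ranged over -0.00110 to 0.504 for MHC class I and -0.0638 to 1.17 for NK markers in T cells. For G2M genes in NK or ILC1 cells the range was -0.985 to -0.0129. Over all settings, values of single named genes kept direction and side of the threshold 3731 times and lost their call 1275 times, and those of single lists 1114 and 546 times.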

Other observations

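Members of lists not described so far moved in stromal cells, while none of these lists passed as a whole (camera in limma). Smooth muscle actin Acta2 and transgelin (Tagln), genes of the contractile cytoskeleton, fell by 2.29 and 1.38 on the log2 scale in knockouts from 10.4 and 29.5 CPM in controls. These levels are low beside the 1697 and 1203 CPM of pericytes (mean of Acta2 and of Tagln over the mice), and smooth muscle cells made up 0.135 ± 0.106% of knockout and 0.252 ± 0.163% of control cells. The alarmin Il33 and the macrophage growth factor Csf1 fell by 1.09 and 0.47, 2 of 12 inflammatory cytokines (0 rose; 3 fell adjusted over the list alone; adjusted p = 0.110). For the 8 smooth muscle markers 1 rose and 2 fell (1 and 3 adjusted over the list alone; adjusted p = 0.315). The vessel growth factors Angpt2 and Vegfc and the receptor Nrp2 rose by 1.32, 0.80 and 1.17, 3 of 17 genes of angiogenesis (0 fell; the same adjusted over the list alone; adjusted p = 0.0666). Of 20 genes of TGF-beta and BMP signalling 2 rose, Bmp4 (1.48) and Tgfb3 (0.61), and the BMP inhibitor Smad6 fell (-1.01; the same adjusted over the list alone; adjusted p = 0.339). Of 16 genes of the list of Lcn2 and iron handling in stromal cells 1 rose and 4 fell, Lcn2 itself included (2 and 5 adjusted over the list alone), with the ferritin Fth1 at -0.57, the iron transporter Slc11a2 at -0.54 and Bdh2 at 0.67. The list did not pass (camera in limma, adjusted p = 0.293).

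All 35 splits of the 7 mice into 4 and 3 were fitted for each count. The real grouping alone gave the largest count for stromal cells (3068 genes against 2 in the next), dendritic cells (53 against 25) and mesothelial cells (198 against 74). It also did for luminal cells (60 against 49) and the lists (123 against 115), by a narrow margin, and every other split called from 44 to 115 lists. Being the highest of 35 splits is an exact permutation p of 0.0286 for a count taken alone. With no adjustment for the 14 counts examined, chance is not excluded for any of them. Counts as large came from 2 splits, the real one included, for lymphatic endothelial cells (81 against 93) and from 6 for plasma cells (1 against 8). They came from 3 for macrophages (8 against 61), pericytes (2 against 9) and vascular endothelial cells (1 against 62). In these classes chance cannot be excluded even for a count taken alone. For glandular, NK or ILC1 and T cells the real count was 0, which all 35 reached, with highest others of 24, 0 and 3; edgeR had 318, 1413 and 388 genes there at an unadjusted p under 0.05 and DESeq2 called 2, 5 and 16. The splits with 93 lymphatic and 62 vascular genes put knockout 4 and knockout 1 with the controls, and that with 61 macrophage genes joined knockouts 2 and 3 with controls 1 and 2. The split with knockout 4 among the controls also gave the 49 luminal and 74 mesothelial genes. Whether a structure of the samples beside the genotype lies behind these counts was not tested.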
